A study of Drosophila melanogaster with 3 samples.

How the data were processed

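RNA was measured in 3 libraries from Drosophila melanogaster males aged 10 days, in which RNA interference (RNAi) against the transcription factor gene Ptx1, the fly Pitx gene, was directed to skeletal muscle. Per the labels' protocols, total RNA was isolated with an RNeasy kit, and polyadenylated RNA was made into stranded TruSeq libraries that were sequenced as pairs of 100 base reads. The labels name the 3 libraries as separate samples of a single group and do not say whether they came from separate pools of flies, so every spread given here is between these samples and may be partly technical.

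The deposited values are whole-number counts per gene, with gene symbols and no normalization, as the files themselves show. Per the submitters' processing notes, CASAVA 1.7, BWA, STAR and HTSeq were named, without the role of each. The same notes name mm9, which is a build of the mouse genome, whereas the rows carry fly gene symbols, so the fly build and annotation behind the counts are not known from the sources used here and no coordinates are given. Whether the counting used the strand of the reads is not given in the sources used here, so counts of genes that overlap or lie antisense to each other are uncertain. Counts of close paralogs, such as alphaTry and betaTry, Amy-p and Amy-d, or members of the actin, Jonah and Hsp70 families, are uncertain for the same kind of reason.

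Each file listed 15682 genes, of which 1803 had no count in any library, and 5 summary rows that name no gene and were left out of totals and tests. The genes of libraries 1, 2 and 3 held 35988267, 50794384 and 52675322 counts, or 78.0%, 74.9% and 75.2% of all that the files listed. Of the listed total in the same order, 9.80%, 11.9% and 11.6% lay in no annotated feature, 8.37%, 9.85% and 9.64% did not align uniquely, 2.74%, 2.35% and 2.44% were ambiguous between genes, and 1.07%, 1.08% and 1.14% did not align. A count of 0 allowed a level of up to 0.0834, 0.0591 and 0.0570 CPM in libraries 1, 2 and 3, taken as 3 counts of the total. Intervals of single values and of ratios of summed counts are exact Clopper-Pearson intervals at 95%; they and the limits at a count of 0 cover counting error only, not variation between samples.

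The series describes a comparison with control libraries of another series. The 6 further columns of per-sample values belong to samples outside those described for this series and were not used, in any step. No comparison of RNAi with control was made, no fold change of the target gene is given, and such a comparison would in any case have set libraries of different series against each other. All results therefore describe the 3 RNAi libraries and the differences between them.

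CPM values were computed from the deposited counts by dividing each count by the total of all genes in its library and scaling every library to the same round total. A gene was called detected at 1 CPM or more in every library. The 30 gene lists covered the target, muscle, metabolism, proteases, protein quality control, stress, immunity, translation, regulation, other cell types and sex, and were fixed with the tests before the data were examined. Of 406 list entries, 400 matched a row, 54 of them through names in the RefSeq gene table of the Release 6 plus ISO1 MT assembly, and 6 remained unmatched. These 6 stand in the files under older names (ATPsyn-beta, CG3560, PyK, CG6194, CG8678 and CG3523), which was found after the data had been examined, so they were added in an alternative only. Mgtor was dropped from the gut list after matching, because the symbol belongs to Megator, a nuclear pore protein, and its entry was an error. A further 9 lists were written after the data had been examined.

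For each list with at least 5 detected members, the median of log2(mean CPM + 0.5) over its detected members was placed among 10000 random lists of the same size drawn from the detected genes. For each list and library, the median deviation of log2(CPM + 0.5) of detected members from the gene's mean over the libraries was placed among 10000 random lists matched on mean expression in 20 bins. The smallest p-value these permutations can give is 0.0002, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over 25 lists and over 75 combinations of list and library. Lists written later formed a separate family of 18 combinations, without the list of photoreceptor genes picked for their difference; with it the family had 21 combinations and gave smaller adjusted values, which are not used. Genes are not independent replicates, so these values describe these libraries. Genes that differed between the libraries by more than genes of like abundance were found with edgeR, using an intercept-only fit, TMM factors, filterByExpr, trended dispersion and a chi-square goodness-of-fit test on 2 degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were tested among these genes with a one-sided Fisher's exact test over 33 lists.

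The text names Ptx1, white, the sex genes, the 10 genes with the highest mean CPM, the top 3 members of each list or 6 for protease lists, all members of lists of 6 or fewer genes, and the 10 variable genes with the largest range of log2 CPM among those with a mean of at least 5 CPM. Not every gene that rule allows is named, and genes named outside it, in any part of the text, were chosen after their values were seen. The tests were run on simulated data. With 10522 genes and 50 genes raised in 1 library at each size, the goodness-of-fit test recovered 0 at 1.5-fold, 8 at 2-fold, 50 at 4-fold and 50 at 8-fold, and called 0 of 10322 unchanged genes. With 9579 genes at a dispersion of 0.01, the list test recovered 40 of 40 lists of 20 genes raised 1.25-fold in 1 library. It called 2 of 40 unshifted lists. For the measured libraries, edgeR gave a common coefficient of variation of 0.145, which is the square root of the dispersion. The simulated dispersion was therefore below that of the data. These list counts do not give the power or the rate of false calls of the list tests reported here.

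Alternatives were other scalings, other limits on low values, another pseudocount, another dispersion and leaving out each library. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.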

Results

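Gene expression was measured in 3 libraries of skeletal muscle from male flies aged 10 days that carried RNAi against Ptx1, a homeodomain transcription factor of the PITX family. The title of the series links these factors to protease expression and protein quality control in aging. The libraries held 35988267, 50794384 and 52675322 gene counts. At 1 CPM or more, 9579 genes were detected in every library. All mean values are given ± SD over these libraries, with n = 3.

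The target gene, Ptx1, was still counted in every library. Its counts were 565, 625 and 640 in libraries 1, 2 and 3, or 15.7, 12.3 and 12.2 CPM, with a mean of 13.4 ± 2.01 CPM. The exact 95% interval of library 1 was 14.4 to 17.0 CPM and that of library 2 was 11.4 to 13.3 CPM, which do not overlap. The edgeR goodness-of-fit test did not call Ptx1 variable. Without control libraries, these levels do not show how far the RNAi lowered the transcript. Genes of tissues other than the targeted muscle were counted too, so the tissue that these Ptx1 counts came from is not known. The white gene (w), whose mini-gene marks many transgenes, stood at 1.24 ± 0.278 CPM. The male-specific dosage compensation RNAs roX1 and roX2 reached 697 ± 82.8 and 20.1 ± 0.806 CPM, whereas the yolk protein genes Yp1, Yp2 and Yp3, which are female genes, stood at 1.41 ± 0.177, 0.821 ± 0.0943 and 1.83 ± 0.144 CPM.

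Genes of muscle contraction and energy supply were among the most abundant. The highest mean level was that of CG16826, at 11654 ± 538 CPM, followed by the glycolytic aldolase Ald at 7847 ± 717 CPM and the translation elongation factor gene Ef1alpha48D at 6473 ± 335 CPM. Further genes among the top 10 were Rfabg, which encodes the apolipoprotein of the main lipid carrier of the blood, at 5717 ± 421 CPM, CG1678 at 5691 ± 627 CPM, the aconitase gene Acon at 5621 ± 208 CPM, lcs at 5319 ± 495 CPM, the calcium pump gene Ca-P60A at 5213 ± 70.3 CPM, CG43897 at 5143 ± 142 CPM and the oxoglutarate dehydrogenase gene Nc73EF at 4760 ± 399 CPM. The 29 sarcomere genes held 3.84 ± 0.173% of all gene counts, led by myosin heavy chain (Mhc) at 4492 ± 365 CPM, Mf at 4406 ± 216 CPM and the projectin gene bt at 3520 ± 955 CPM. The 31 measured genes of oxidative phosphorylation, a list of the respiratory chain, ATP synthase and a nucleotide carrier, held 3.69 ± 0.223%, led by the adenine nucleotide carrier sesB at 4032 ± 128 CPM. The 12 measured glycolytic genes held 1.66 ± 0.0540%. With list entries found under older names after the data had been examined, the first share was 4.19 ± 0.208%, with ATPsyn-beta at 3885 ± 245 CPM and CG3560 at 1074 ± 82.5 CPM, and the second 1.80 ± 0.0538%, with PyK at 1447 ± 39.2 CPM.

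Among genes that tell muscle types apart, the fibrillar list, which marks indirect flight muscle, held TpnC4 at 621 ± 43.7 CPM, fln at 330 ± 20.9 CPM, Strn-Mlck at 1331 ± 192 CPM, salm at 38.5 ± 3.94 CPM and the flight muscle actin Act88F at 102 ± 9.74 CPM. The tubular muscle genes Act79B and TpnC41C stood at 878 ± 67.1 and 291 ± 14.6 CPM. Summed counts of Act88F, fln and TpnC4 were 0.903 ± 0.0904 times those of Act79B and TpnC41C, with ratios of 0.801, 0.935 and 0.973 in libraries 1, 2 and 3. Counts were not corrected for gene length, reads shared between the actin genes make the levels of Act88F and Act79B uncertain, and no test was run on this ratio.

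Against random lists of detected genes, 15 of 25 tested lists stood high and none stood low at an adjusted p below the threshold with all libraries, whereas without library 1, 13 stood high and 1, the antimicrobial list, stood low. Only detected members entered this test, such as 14 of 19 antimicrobial and 12 of 18 serpin genes, which limits how low a list could stand. The sarcomere, oxidative phosphorylation, glycolysis, antioxidant, ribosomal protein, reference gene and gut lists each lay at the 100th percentile (adjusted p = 0.000714 in the random-list permutation test, from the smallest raw p it can give). The fibrillar muscle list lay at the 99.8th percentile (adjusted p = 0.00875, permutation test). Ribosomal protein, reference and gut lists thus ranked as high as the sarcomere list, so a high rank is not particular to muscle. Without control libraries, a high rank of any list does not show an effect of the RNAi either. The list of transcription factors of muscle and stress responses, led by crc and Xrp1 at 1129 ± 18.6 and 952 ± 49.3 CPM, lay near the top as well (adjusted p = 0.00278). The 48 ribosomal protein genes held 4.47 ± 0.504% of counts, led by RpL5 at 2208 ± 137 CPM, and the antioxidant list was led by GstD1, a glutathione transferase gene, at 880 ± 81.8 CPM and the catalase gene Cat at 621 ± 10.4 CPM.

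**Figure D1:**
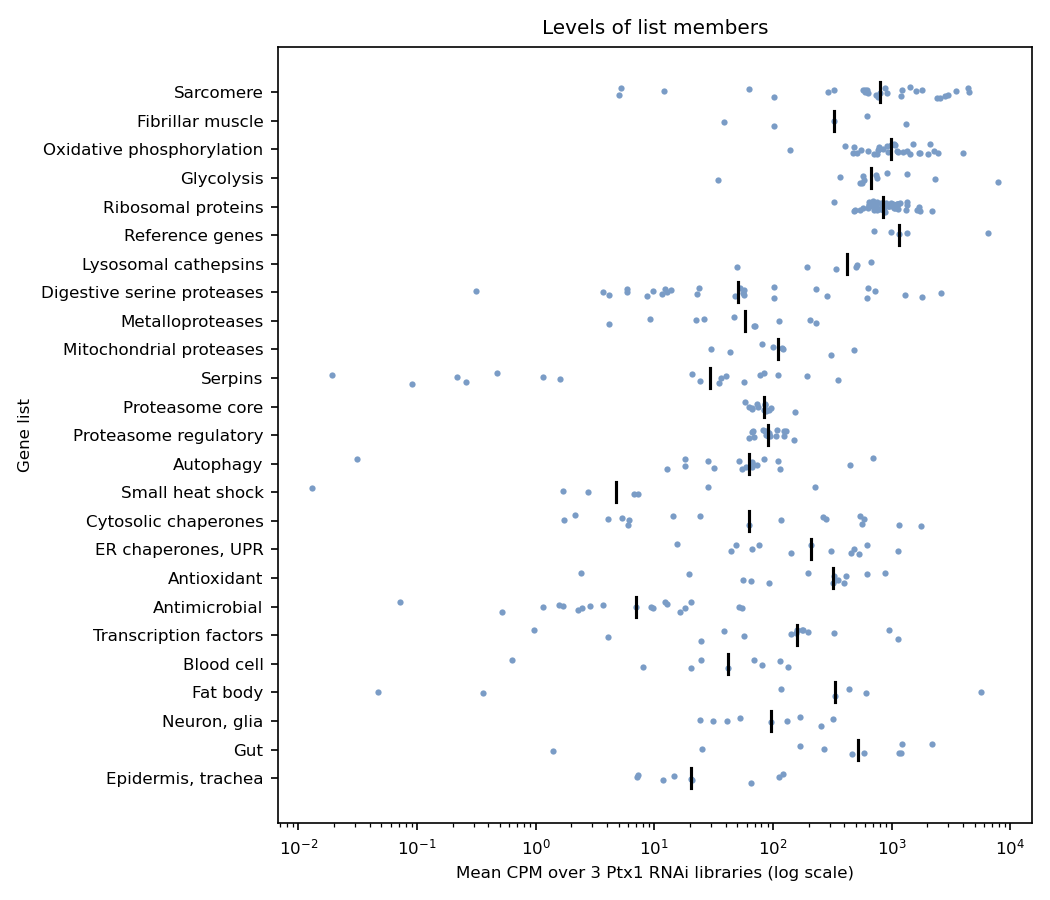
Mean CPM over the 3 Ptx1 RNAi libraries (horizontal log axis) of each gene with a count in the lists with at least 5 detected members; each point is a gene, the height of points within a row is arbitrary, and bars mark the median over all measured members. Members of the sarcomere list have a median of 800 CPM and those of the small heat shock list a median of 4.74 CPM.

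The protease lists covered several cell compartments. The lysosomal cathepsins stood high as a list (adjusted p = 0.00300, random-list permutation test), with the cathepsin L gene Cp1 at 666 ± 6.59 CPM, cathD at 509 ± 48.7 CPM, CG12163 at 505 ± 8.01 CPM, CtsB1 at 342 ± 3.75 CPM, 26-29-p at 193 ± 7.19 CPM and Swim at 49.4 ± 8.48 CPM. The list of mitochondrial proteases, in which the catalytic role of each member was not checked, was led by CG4538 at 482 ± 23.9 CPM. It also held CG6512 at 307 ± 3.74 CPM and Lon at 119 ± 4.44 CPM. This list passed the threshold at an adjusted p of 0.0473 in the permutation test and missed it without library 1 (0.0522) or without library 3 (0.0510). The metalloproteases were led by Ance and Acer, relatives of angiotensin-converting enzyme, at 230 ± 2.12 and 206 ± 9.64 CPM, with Mmp1 at 113 ± 1.01 CPM and the neprilysins Nep4, Nep2 and Nep3 at 70.4 ± 1.59, 69.2 ± 6.09 and 46.7 ± 8.51 CPM, and their list did not pass the threshold (adjusted p = 0.270). The serpins, most of which inhibit serine proteases, did not pass either (adjusted p = 0.359), with Spn43Ab at 356 ± 15.4 CPM and nec at 193 ± 11.8 CPM as the highest members.

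The 28 trypsin and Jonah family serine proteases, which are gut genes, held 0.881 ± 0.138% of counts. The highest were alphaTry at 2595 ± 194 CPM, betaTry at 1810 ± 193 CPM, Jon65Aiv at 1302 ± 425 CPM, Jon99Cii at 721 ± 69.1 CPM, Jon65Aiii at 638 ± 199 CPM and Jon99Ciii at 619 ± 67.0 CPM. As a list they did not stand apart from random lists of detected genes (adjusted p = 0.115, permutation test), and they did with a background of all genes with a count (adjusted p = 0.00684).

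In protein quality control, both proteasome lists and the endoplasmic reticulum list stood high. The core subunits were led by Prosbeta5 at 155 ± 13.7 CPM, Prosalpha7 at 96.4 ± 8.33 CPM and Prosbeta7 at 92.4 ± 7.50 CPM (list adjusted p = 0.0432, and 0.0559 without library 1, permutation test). The regulatory subunits were led by Rpn2 at 152 ± 1.87 CPM, Rpn6 at 129 ± 1.08 CPM and Pros45 at 124 ± 12.7 CPM (list adjusted p = 0.0192, permutation test). The endoplasmic reticulum list (adjusted p = 0.00125, permutation test) held Xbp1, a transcription factor of the unfolded protein response, at 617 ± 45.8 CPM and Pdi, a protein disulfide isomerase gene, at 526 ± 31.2 CPM. The autophagy list did not pass the threshold (adjusted p = 0.0971, permutation test), with Atg8a at 700 ± 24.3 CPM, the adaptor gene ref(2)P at 443 ± 11.8 CPM and Atg2 at 115 ± 8.08 CPM. Neither did the cytosolic chaperones (adjusted p = 0.119, permutation test), with Hsc70-4 at 1781 ± 107 CPM, Hsp83 at 1165 ± 6.75 CPM and Droj2 at 590 ± 25.3 CPM, nor the small heat shock genes (adjusted p = 0.0575, permutation test), with l(2)efl at 226 ± 35.9 CPM, Hsp26 at 28.5 ± 3.64 CPM and Hsp67Ba at 7.34 ± 0.681 CPM. With a background of all genes with a count, the autophagy and cytosolic chaperone lists passed (adjusted p = 0.00877 and 0.0111, permutation test).

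Genes of other tissues were counted as well. The gut list, without its serine proteases, held 0.730 ± 0.0684% of counts, with the maltase genes Mal-A1 and Mal-A6 at 2185 ± 325 and 1211 ± 36.1 CPM and the amylase gene Amy-p at 1228 ± 92.0 CPM. The fat body list (adjusted p = 0.00455, permutation test) held 0.722 ± 0.0432%, with Lsd-1 at 613 ± 77.7 CPM and Lsp2 at 438 ± 38.5 CPM, and 0.935 ± 0.0331% with the fatty acid synthase gene CG3523, found under its older name after the data had been examined, at 2126 ± 102 CPM. Neuron and glia genes held 0.112 ± 0.0224%, led by Syt1 at 322 ± 77.7 CPM (list adjusted p = 0.0725, and 0.0111 with a background of all genes with a count, permutation test). Blood cell genes held 0.0495 ± 0.00505%, led by crq at 133 ± 6.99 CPM (list adjusted p = 0.354, permutation test), and epidermis and trachea genes held 0.0384 ± 0.00559%, led by Ddc at 122 ± 10.5 CPM (list adjusted p = 0.540, permutation test). The antimicrobial list held 0.0228 ± 0.00457%, with PGRP-SB1 at 54.4 ± 8.65 CPM and Drs at 51.3 ± 1.28 CPM (list adjusted p = 0.0588, and 0.0286 on the low side without library 1, permutation test). Of 12 testis and accessory gland genes, 1 was detected, twe at 1.48 ± 0.114 CPM.

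Set against counting error alone, which separate samples are expected to exceed, the chi-square per degree of freedom between libraries was 103 for libraries 1 and 2, 42.5 for libraries 1 and 3 and 23.2 for libraries 2 and 3. Among 10522 genes tested with edgeR, 216 differed between libraries by more than genes of their abundance did, and 567 did so at an unadjusted p below the threshold. Of the 216 genes, 137 were highest in library 1 and lowest in library 2, and 78 were highest in library 2 and lowest in library 1. The count was 108 without library 1, 89 without library 2 and 124 without library 3. These genes were found from the libraries they describe, and they are not independent of each other.

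Digestive serine proteases formed the fixed list with the most variable members. Of 27 members tested, 13 were variable over all genes and 16 when adjusted over the list alone, and all 13 were highest in library 1 (Fisher's exact test, adjusted p = 4.1e-14). Leaving out libraries 1, 2 and 3 gave 11, 9 and 11 variable members. Jon99Fi stood at 46.3, 3.07 and 18.7 CPM in libraries 1, 2 and 3, Jon65Ai at 28.5, 2.15 and 10.9 CPM and Jon66Ci at 12.4, 0.610 and 4.58 CPM (edgeR adjusted p = 5.5e-28, 5.1e-22 and 3.0e-19). The more abundant alphaTry and betaTry were not called, at 2816, 2456 and 2512 CPM and at 2032, 1708 and 1689 CPM. Of 17 antimicrobial genes tested, 5 were variable and 7 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.000291), and all 5 were highest in library 1, among them PGRP-SC2, named after its values were seen, at 29.6, 8.66 and 16.1 CPM. The antimicrobial count was 2 without library 1, 0 without library 2 and 2 without library 3. Of 10 gut genes, 2 were variable, the mannosidase genes CG9466 and CG9468, named after their values were seen (Fisher's exact test, adjusted p = 0.140).

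The variable genes with the widest range also included genes that were highest in library 2. CG8343 stood at 0.361, 101 and 62.5 CPM, CG9676 at 1.19, 39.7 and 23.2 CPM, and CG1561 at 0.722, 17.3 and 11.9 CPM in libraries 1, 2 and 3. The stress-induced humoral factor gene TotM stood at 8.42, 150 and 103 CPM and Diedel, an immune-regulated gene, at 1.36, 32.9 and 18.1 CPM. The photoreceptor gene chp stood at 4.17, 50.7 and 33.7 CPM. CG8562 went the other way, at 23.3, 0.768 and 10.0 CPM. The edgeR adjusted p was 7.3e-24 or smaller for each of these 7 genes.

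**Figure D2:**
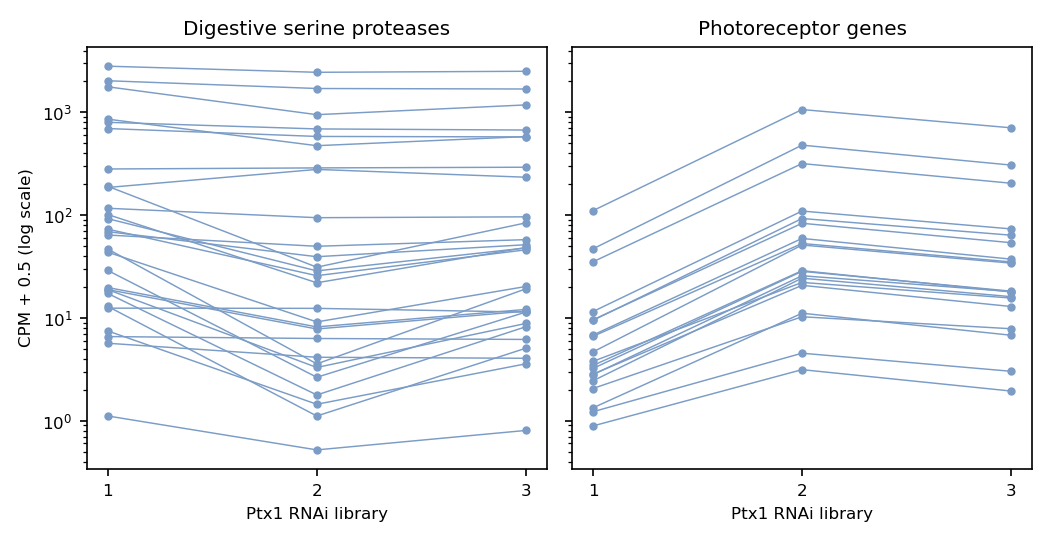
CPM + 0.5 (vertical log axis) of 28 digestive serine protease genes and of 19 photoreceptor genes in the 3 Ptx1 RNAi libraries; each line joins the values of a gene, and the order of the libraries has no meaning. The photoreceptor genes were picked from the variable genes, so their common direction is a matter of choice; among the proteases, Jon99Fi lies at 46.3 CPM in library 1 and at 3.07 CPM in library 2.

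As whole lists, 8 of 25 lists deviated from their mean in at least 1 library, with 19 of 75 combinations of list and library past the threshold. Each gene's deviations from its own mean cancel out over the libraries. The values of a list in libraries 1, 2 and 3 are therefore tied, and its passes in different libraries are not separate results. Digestive serine proteases deviated by 0.47 in library 1 and −0.40 in library 2 on the log2 scale, and antimicrobial genes by 0.33 and −0.31 (adjusted p = 0.00115 for each, permutation test). Ribosomal proteins deviated by 0.19 and −0.15, core proteasome subunits by 0.17 and −0.16, and gut genes by −0.16 in library 2, at the same adjusted p. Regulatory proteasome subunits deviated by 0.12 and −0.11 (adjusted p = 0.00200, permutation test). Neuron and glia genes had the opposite signs, at −0.32 in library 1 and 0.28 in library 2 (adjusted p = 0.00115, permutation test). Oxidative phosphorylation genes deviated by 0.12 in library 1 and −0.03 in library 3 (adjusted p = 0.0474 and 0.0234, permutation test). In library 3, digestive serine proteases, ribosomal proteins and core and regulatory proteasome subunits deviated by −0.04, −0.04, −0.02 and −0.01 (adjusted p = 0.00115, 0.00115, 0.0274 and 0.0450, permutation test), of which the digestive value was 1.8e-05 with a background of all genes with a count (adjusted p = 0.622). The sarcomere list deviated by 0.02, −0.02 and 0.01 in libraries 1, 2 and 3 and passed in none (adjusted p = 0.824, 0.735 and 0.735, permutation test). A list of genes outside the sarcomere, written after the data had been examined and meant for very large proteins, though not all of its members are, deviated by −0.30 in library 1 and 0.25 in library 2 (adjusted p = 0.00180, permutation test). Of the sarcomere genes, bt stood at 2544, 4452 and 3566 CPM in libraries 1, 2 and 3 (edgeR adjusted p = 0.297) and sls, named after its values were seen, at 2036, 3594 and 2799 CPM. Transcript lengths were not used here, and the random lists were matched on mean expression only. Whether the list deviations follow transcript length was therefore not tested.

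**Figure D3:**
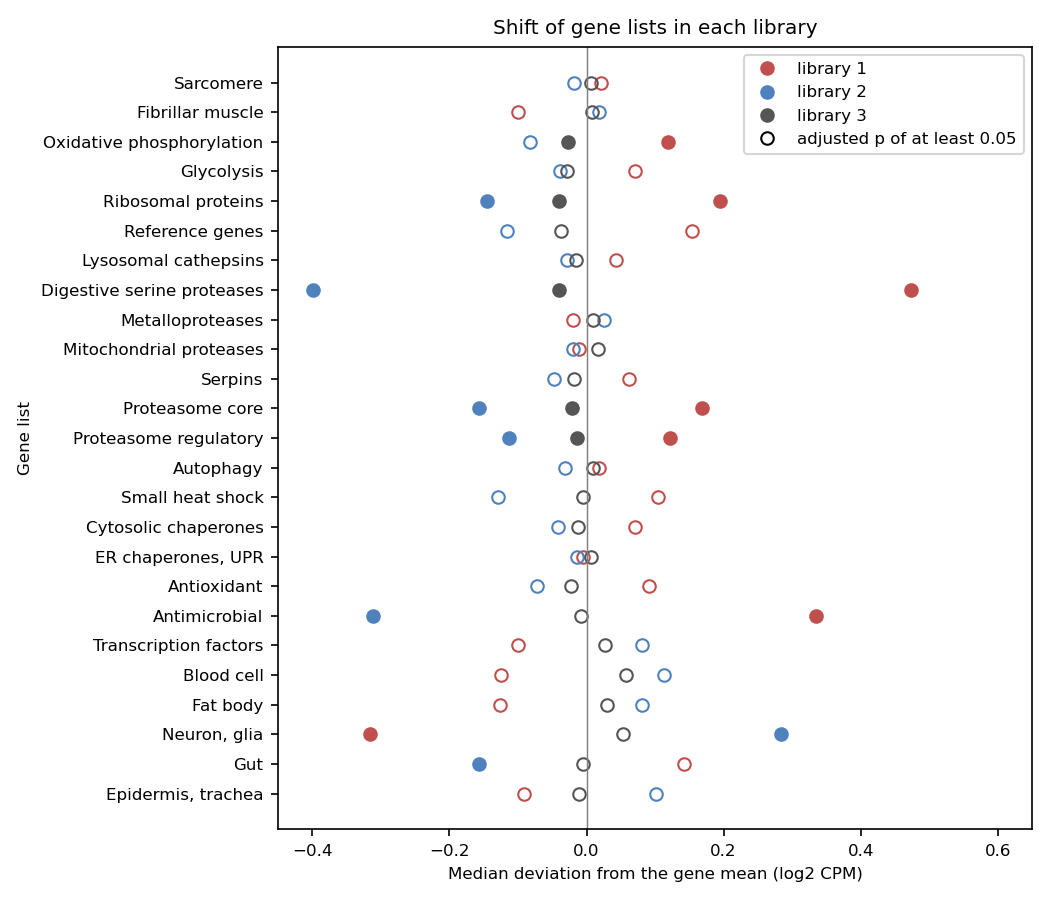
Median deviation of each list from its genes' means in log2 CPM (horizontal axis) for libraries 1, 2 and 3 (colours); filled points passed the threshold and open points did not. Digestive serine proteases lie at 0.47 in library 1 and −0.40 in library 2, and neuron and glia genes at −0.32 and 0.28.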

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

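The number of variable genes was 216 with all libraries and between 89 and 124 with 1 library left out, where fewer libraries and 1 degree of freedom remain, and of the 108, 89 and 124 genes called without libraries 1, 2 and 3, 106, 85 and 124 were among the 216. It was 210 with DESeq2 size factors (207 shared), 262 with no filter on low counts (187 shared) and 244 with a common dispersion (206 shared). The sarcomere share was 4.10% when the 10 most abundant genes were left out of the totals, as a smaller total requires. The deviation of digestive serine proteases in library 3 changed sign, from −0.04 to 1.8e-05, with all genes with a count (adjusted p = 0.622, permutation test), and the cause was not tested. With all libraries 15 lists stood high and 0 low; it was 19 and 0 with a background of all genes with a count, 15 and 0 with a pseudocount of 1, 13 and 1 without library 1, 15 and 0 without library 2, and 14 and 0 without library 3. With older names for the 6 unmatched list entries, an alternative chosen after the data had been examined, 15 lists stood high and 19 list deviations passed, as before. Of results for single genes and lists, 1267 kept their side or stayed within 1 SD, 6 passed the threshold only under an alternative, 3 missed it under one, 1, the digestive deviation above, changed sign, and 62 moved by more than 1 SD, which were 45 gene levels and 13 list shares with totals without the 10 most abundant genes and 4 list shares with the older names. Ptx1 ranged from 12.2 to 14.3 CPM over all alternatives run, and genes detected from 8241 to 10005. The planned values per kb of exon, for list levels and for the muscle type ratio, were not run, because no exon lengths were at hand. With a single group there was no paired fit to make. With these libraries and the dispersion estimated from them, changes of 2-fold in 1 library were mostly missed in the simulation. A gene that was not called is therefore not shown to be equal between libraries.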

Other observations

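Lists written after the gene levels had been examined describe further muscle biology. The 11 tricarboxylic acid cycle genes held 1.81 ± 0.0546% of counts (SD, n = 3), with SdhA at 2023 ± 74.8 CPM and SdhB at 1427 ± 89.4 CPM. The calcium and phosphagen list held 1.21 ± 0.00804%, with arginine kinase (Argk) at 3044 ± 198 CPM and the calcium-binding protein gene Scp1 at 2215 ± 106 CPM. Among clock genes, cry stood at 245 ± 9.80 CPM, vri at 234 ± 6.01 CPM and per at 22.3 ± 0.649 CPM. In the insulin and TOR list, Thor, the 4E-BP gene, stood at 467 ± 4.72 CPM, and InR was its only variable member, at 13.2, 29.5 and 23.4 CPM in libraries 1, 2 and 3 (edgeR adjusted p = 0.0245). Of 27 genes in a list meant for very large proteins outside the sarcomere, 5 were variable (Fisher's exact test, adjusted p = 0.00214), a count that was 0 without library 2 or without library 3 and 2 without library 1. Not all members of that list are very large, and transcript lengths were not used here.

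The tests of scaling, of a shared gut ratio and of mixed RNA were chosen only after the results they measure had been seen. The 3 patterns below were found in the same libraries in which they were tested, the libraries form a single group, and no biological explanation was tested.

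Photoreceptor genes, noticed among the variable genes, stood higher in library 2 than in library 1, with the opsin gene ninaE at 110, 1066 and 708 CPM in libraries 1, 2 and 3. The median log2 ratio of library 2 to library 1 over all 9579 detected genes was −0.0202, so most detected genes did not share this difference. CPM divides each library by its own total, which keeps this median small in advance. This median therefore cannot decide on a scaling difference. A single scaling factor would, however, move all genes alike. The 19 noticed genes had a median log2 ratio of 3.12, and 13 of the 14 further genes below were higher in library 2. Ribosomal protein genes had a median of −0.33, with 0 of 48 higher. These values argue against a single scaling factor as the source of the difference in these photoreceptor genes. Over 14 further photoreceptor genes chosen without looking at them the median was 0.60 (95% bootstrap interval 0.37 to 1.09), with 13 of 14 higher in library 2. Of 12 tested, 2 were variable (Fisher's exact test, adjusted p = 0.160). The 11 detected members deviated by −0.26, 0.25 and 0.08 in libraries 1, 2 and 3 (adjusted p = 0.00270, 0.00270 and 0.00288, permutation test). The 19 noticed genes, all of them variable, had been set apart before this list was written. That tends to lower the list's median and its count of variable members, so neither speaks against eye tissue. The median lay below the 1.5 set for eye tissue and not below the 0.5 set against it. Members ranged from the opsin gene Rh2, with 1, 429 and 323 counts, to rdgA, CdsA and santa-maria, at 155, 96.3 and 81.9 CPM in library 1 already. Unequal amounts of eye tissue therefore remain open. Over 7 antenna and brain genes, chosen in the same way, the median was 1.07 (0.17 to 2.10), with 6 of 7 higher in library 2. This was past the 0.5 set for other head tissue, with an interval that reaches below it. The fixed neuron and glia list, which is not limited to the head, had 9 of 9 higher and a median of 0.65. Lists not chosen for the head moved the same way, with 8 of 9 blood cell and 8 of 9 epidermis and trachea genes higher. So did 13 of 14 transcription factors and 26 of 27 genes of the list meant for very large proteins. Other lists did not, with 13 of 29 sarcomere and 0 of 48 ribosomal protein genes higher. Other head tissue stays open as a source, since the members that moved most had low counts. In libraries 1, 2 and 3, a10 had 3, 206 and 149 counts and Orco 3, 102 and 45. Pbprp4 had 0, 31 and 23, and Obp19a, which holds the median, 0, 28 and 25. Pdf, lush and Pbprp3 moved less, at 30.3 and 28.2, 6.09 and 6.93, and 8.17 and 11.9 CPM in libraries 1 and 2. The median over the 13 further genes with a mean of 10 counts was 0.69, and the SD of the ratio over the 19 noticed genes was 0.47, and neither is used as evidence, since the first filter was not planned and the second set was picked for its difference.

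Of 27 digestive serine proteases tested 13, and of 10 gut genes 2, were variable and highest in library 1, and 2 of all 28 proteases and 3 of the 10 gut genes were higher in library 2 than in library 1. If a single gut tissue carried over in unequal amounts were the only source of these protease genes, they would share a ratio. The SD of their log2 ratio over 27 genes was 1.27 (95% bootstrap interval 0.98 to 1.47), which argues against it as the only source. The genes alphaTry and betaTry were high in every library, so gut tissue added to a level common to all libraries stays open. Differences between gut regions or states stay open as well. Testis tissue carried over with the gut was tested with 39 further testis genes, whose summed CPM was 1.34 times higher in library 1 (exact 95% interval 1.26 to 1.42), short of the 2 set for it and below the 1.5 set against it. That bound does not decide, because 3 members with a similar level in every library, m-cup, mia and topi, held 92.5% of the counts in library 2. The other 36 had 548, 165 and 423 counts in libraries 1, 2 and 3, a ratio of 4.69 (3.93 to 5.61), a split made after the values were seen, and since both intervals cover counting error only, this source remains open.

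Library 3 lay between the other libraries in 215 of 216 variable genes, where random order would give 33.3%, although genes picked for a wide difference between libraries 1 and 2 tend to place library 3 between them. Pooled reads of libraries 1 and 2 are argued against, since library 3 differed from their best mixture, with a fraction of 0.61 from library 2, by a chi-square per degree of freedom of 4.88, above the 2 set against it. Mixed RNA could not be excluded: median fractions were 0.601 in photoreceptor, 0.668 in digestive protease and 0.714 in ribosomal protein genes, and the largest difference was 0.11 (95% bootstrap interval 0.06 to 0.16), past the 0.1 set for it, with an interval that includes 0.1. With the members limited to at least 100 counts and a log2 ratio beyond 0.2, the largest difference was 0.13 (0.06 to 0.17).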
